A study of Mus musculus with 20 samples.

How the data were processed

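Genomic DNA from the tails of 10 C57BL/6 mice of 1 family, a sire, a dam and 8 progeny, was measured by 2-colour comparative genomic hybridisation on a custom oligonucleotide tiling array. Each mouse was hybridised 2 times against the same reference male, once with the mouse in Cy5 and once with the mouse in Cy3, per the labels. This gave 20 arrays on 5 slides of 4. The 2 arrays of a mouse are a technical dye swap and were counted as 1 replicate. Both parents were on 1 slide and no progeny was, so slide and generation cannot be told apart. The series title names males exposed to gamma rays at 1 mGy per day for 400 days, while the design text calls the male of this family non-irradiated. No comparison of exposure was made.

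The deposited spot intensity values were made with Agilent Feature Extraction 10.7.1.1, per the file headers, which also give a linear dye normalization and coordinates on mouse build mm9. The processed signals are background-subtracted and dye-normalized intensities, per the file headers. The deposited log10 ratio of red over green was used only to find the scale and direction of the authors' value table. The authors' deposited table holds log2 ratios, and all 20 of its columns were used. Set against the scanner's log10 ratio, its slope was 3.11 to 3.28 on arrays with the mouse in Cy3 and -3.32 to -3.23 on arrays with the mouse in Cy5, so it runs as reference over mouse on every array. In the order sire, dam and progeny 1 to 8, its column medians were 0.0089, -0.00091, 0.0092, 0.0095, 0.0091, 0.0082, 0.0095, 0.0094, 0.011 and 0.016 with the mouse in Cy3, and -0.0035, 0.0082, 0.0078, 0.0072, 0.0062, 0.0068, 0.0069, 0.0071, 0.0095 and 0.014 with the mouse in Cy5. A further correction separates it from the processed signals, and what that correction was is not given in the sources used here. How the medians were centred also stays unknown.

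From the processed signals, log2 ratios of mouse over reference were taken, opposite to the direction of the deposited table, and each array was centred on the median of its autosomal probes with no loess or quantile step. The medians removed lay between -0.014 and 0.012. Each array held 137985 spots, of which 6563 were control spots and were left out. Spots marked as outliers by the scanner software, 96 to 303 an array, were also left out, and spots of 1 probe were averaged. Of 127380 unique probes, 127076 were measured on all 20 arrays, 127025 of them autosomal. The X chromosome had 48 probes and the Y chromosome 3, and these entered no main interval or test. They were used in an alternative and, for Y, in the check for DNA of other mice.

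Intervals were called per mouse on the mean of its 2 orientations. A run of adjacent probes was scored as the absolute sum of its log2 ratios over the noise times the square root of the number of probes, with the noise taken from differences between neighbouring probes. A run was called at a score of at least 6, with at least 3 probes, an absolute mean of at least 0.25, and each orientation alone of the same sign and at least 0.25. Runs were broken at gaps over 50 kb. Intervals of the same sign in different mice became 1 region at 50% reciprocal overlap. A region was counted as progeny only where it was called in at least 1 progeny and in neither parent, and where such a progeny differed from each parent by at least 0.25 in both orientations. Calls of opposite sign formed separate regions, so a progeny-only gain could lie where a parent was called for a loss. The background for intervals against the family median was the same caller on the difference between orientations divided by 2. That difference holds dye and array noise, but neither copy number nor anything else that both arrays of a mouse share.

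Probe-wise tests used limma 3.58.1 in R 4.3.3 (lmFit, eBayes, two-sided) with Benjamini-Hochberg adjustment, called at an adjusted p under 0.05 and an absolute change of at least 0.25. One fit compared the 8 progeny with 0 and the other compared 8 progeny with 2 parents. Regions where sire and dam differed by at least 0.5 in both orientations were tested with an exact two-sided binomial test of how many of the 8 progeny lay nearer the sire on the log2 scale, adjusted over regions. Counting progeny nearer the sire, and calling a progeny between its parents when it lay more than 33.3% of the parental difference from each, were fixed after the data were seen, as was the position of the progeny on the linear scale. To describe variation shared over the genome, the 2 leading components over the 10 mice were taken from 3342 isolated probes outside every called interval, and their share in each region was computed with and without removal of the mean over mice, the former chosen after the data were seen. Interval calling and summaries used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and statsmodels 0.14.6, and figures matplotlib 3.10.9.

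The caller was tested on simulated data, 200 runs placed in the orientation noise of progeny 1. For runs of 3 probes it found 99.5% at a change of 0.5 and 47.5% at 0.25. In orientation noise shuffled over mice, the fit of the progeny against 0 found 100 of 100 probes changed by 0.5 over 127025 probes, and the fit of progeny against parents found 99 of 100. Orientation noise holds no variation common to both arrays of a mouse, which the real values contain. These shares are therefore not the power in the real data.

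Regions stand in for genes, because the array files name no genes and the gene table at hand is on another build. The tests, thresholds, alternatives and the naming rule were fixed before the data were examined, except where another time is given. By that rule regions were named by score, up to 10 for each result, and by size of change, up to 25. The chromosome 8 segment and the short regions of the closing section were chosen after their values were seen. The 22 gene lists fixed beforehand were not tested, because no genes could be named. Alternatives covered the background correction (normexp with an offset of 50, on median spot signals), the deposited table, centring, dim probes, single orientations, the thresholds of the caller, slide as a random block and leaving out each progeny. A minimum of 10 probes, leaving out the last slide and including X and Y probes were added after seeing the data. Removal of a trend with GC content was not run, since probe sequences were not used here. Comparisons across probes treat probes as measurements of the same mice, and the number of mice limits the precision.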

Results

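Copy number was measured in tail DNA of a sire, a dam and their 8 progeny, each against 1 reference male of the same colony. The array was not a genome-wide survey. Per the series design, its probes were placed densely around candidates from an earlier screening of the same family, so the counts below are not rates over the genome and the regions are not independent of these mice. It held 1389 stretches of at least 10 probes, with a median of 90 probes over 13210 bp and a median spacing of 92 bp. The median raw spot signal of the mouse channel was 593 to 1902 over a background of 36 to 74, and the last slide, which held progeny 7 and progeny 8, was the dimmest, with array medians of 593 to 1209 over both channels. Each mouse is a single sample, so a value for 1 mouse is given with its 2 dye orientations in place of a replicate error. Positive values mean more DNA in the mouse than in the reference, the opposite sign to the deposited table.

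The first comparison asks which aberrations of the progeny were absent from both parents. Progeny 1 and progeny 3 carried a gain of 106 kb on chromosome 5, from 73670967 to 73777244 on build mm9, measured by 640 probes. The mean log2 ratio was 0.50 in progeny 1, with 0.52 and 0.48 in the 2 orientations, and 0.53 in progeny 3, with 0.54 and 0.52. These are 1.41 and 1.44 times the reference. The same 2 mice carried a second gain of 29.5 kb on chromosome 5, from 77661346 to 77690879 (108 probes), at 0.48 and 0.50. The 275 probes between both segments, which lie 3.88 Mb apart, had means within 0.028 of 0 in every mouse.

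The sire lay at -0.02 in the first segment and -0.01 in the second. The dam was not called in either, but lay at 0.11 in both, with 0.13 and 0.10 in the 2 orientations of the first segment and 0.16 and 0.06 in those of the second. In the dam, 193 uncalled stretches of 640 probes ran from -0.03 to 0.02, and 1146 uncalled stretches of 108 probes from -0.06 to 0.04, so both values exceeded that spread. The other 6 progeny had means from -0.03 to -0.01 in the first segment and from -0.01 to 0.00057 in the second. Progeny 1 and progeny 3 were hybridised on different slides.

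Progeny 7 and progeny 8 carried a loss of 40.2 kb on chromosome 10, from 33894598 to 33934819 (367 probes). The mean log2 ratio was -0.58 in progeny 7, with -0.60 and -0.56 in the 2 orientations, and -0.62 in progeny 8, with -0.64 and -0.60. These are 0.67 and 0.649 times the reference. The sire lay at -0.02 and the dam at -0.0027, and the other 6 progeny between -0.01 and 0.0071. Set against progeny 7, the value of the sire was 3.46% of the change, with bounds of -1.49% and 8.33% at 2 SD of equal stretches, and that of the dam 0.558%, with bounds of -4.04% and 5.09%. Probes within 1 Mb on either side had means within 0.072 of 0. Both carriers were on the last slide. The 2 leading components of isolated probes outside every interval accounted for 55.7% of the sum of squares of this segment over the mice. With the mean over mice removed from the probes and the segment, a choice made after seeing the data, the share was 97.6%. Of random profiles, 95% stayed under 52.7% without that step and 57.1% with it. The share depends only on the values over mice, and the 2 carriers lay highest on the first component, at 0.0458 and 0.444. A loss of this depth in these 2 mice alone would give the same share whatever its cause. The share therefore decides nothing about the cause of this segment.

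**Figure D1:**
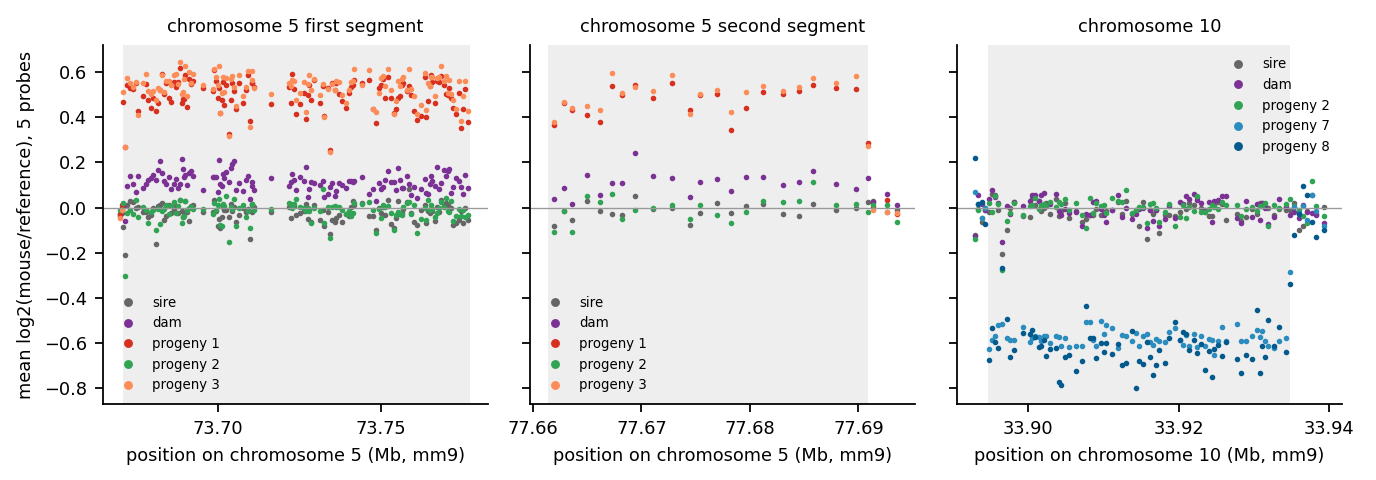
Mean log2 ratio of mouse over reference in blocks of 5 probes (points) against position on mm9 in Mb, for the 2 chromosome 5 segments and the chromosome 10 segment (grey). Progeny 1 and progeny 3 lie near 0.50 on chromosome 5 with the dam near 0.11, and progeny 7 and progeny 8 near -0.6 on chromosome 10, while the sire and progeny 2 lie near 0.

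By the full rule, 322 regions were progeny only, of which 242 were gains and 80 losses. Most were short, and 256 were called in progeny 8 alone. Among the 25 with the greatest change, 23 were gains called in progeny 8 alone, and none had more than 4 probes. The highest was a gain of 1.52 in progeny 8 on chromosome 13, from 112754727 to 112754821 (3 probes), where progeny 1 to 6 lay between -1.32 and -0.94, the sire and dam at -0.66 and -0.89, and progeny 7 at 0.15. Of all 25 regions named by size, in parents or progeny, 19 were gains called in progeny 8 and 6 were losses. The same site can count in both, since gains and losses were merged separately. The chromosome 13 site above was also called as a loss in the sire, the dam and progeny 1 to 6. Progeny only thus does not mean unchanged in the parents. In the 700 regions under 10 probes, the median share of such components was 95.8%, and 95.1% with the mean over mice removed. In the 2 chromosome 5 segments it was 23.9% and 26.7%, and 8.54% and 7.92% with the mean removed. Which mice carry a change sets this share, so it does not tell these gains from the short regions by cause. Of the remaining regions, 248 were called only in progeny but without a measured difference from a parent, 153 in a parent, and 1 in every mouse. With at least 10 probes, an alternative chosen after seeing the data, 12 progeny-only regions were left, 8 of them in progeny 8 alone, and without the 2 progeny of the last slide the count was 64.

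The second comparison asks how copy number differences between sire and dam appeared in the progeny. The dam carried a deep loss of 70.7 kb on chromosome 13, from 101039739 to 101110429 (38 probes), at -2.30, or 0.203 times the reference. The sire lay at 0.02. All 8 progeny carried a shallower loss of -0.63 ± 0.06 (SD, n = 8), and its range was -0.70 to -0.56. On the linear scale the progeny lay 50.8% to 58.2% of the way from dam to sire, and 8 of 8 were past the midpoint. With the normexp correction the dam lay at -1.66, the progeny at 42.1% to 49.6%, and 0 of 8 were past the midpoint, so the side of the midpoint depends on the background correction. On the log2 scale 8 of 8 progeny were nearer the sire (two-sided exact binomial p = 0.0078, adjusted p = 0.047 over 6 regions). That count is set by the scale, since a mouse midway on the linear scale would lie at -0.71 and the midpoint on the log2 scale was -1.14, so the p is not read as a departure from an even split. An overlapping region of 10 probes, from 101021060 to 101052188, gave -0.63 in the dam, 0.02 in the sire and -0.28 ± 0.02 (SD, n = 8) in the progeny. There 7 of 8 were nearer the sire on the log2 scale (exact binomial p = 0.070, adjusted p = 0.21) and 2 of 8 on the linear scale.

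On chromosome 3, a loss from 25421508 to 25443259 (10 probes) lay at -1.56 in the dam and at -1.67, -1.65, -1.40 and -1.40 in progeny 5, 6, 7 and 8. The sire lay at 0.02 and progeny 1 to 4 between -0.0022 and 0.01, a split of 4 against 4 (exact binomial p = 1). The 10 probes differed widely, with a standard error of 0.30 over probes in the dam. On chromosome 8, a segment of 22 probes from 102191370 to 102205592 lay at 0.23 in the dam, 0.27, 0.28, 0.18 and 0.20 in progeny 5 to 8, and 0.0082 to 0.02 in the other mice. It was called in progeny 5 and progeny 6 alone, and was chosen after its values were seen. The dam and progeny 5 to 8 were also the mice with X-chromosome log2 ratios of 0.96 to 0.98 and Y-chromosome log2 ratios of -4.68 to -3.78. That is 1.95 to 1.97 times the X signal of the reference male. These mice thus had the X and Y values of females, and the others those of males. The chromosome 3 and chromosome 8 values split exactly by sex, and the chromosome 3 loss was about as deep in progeny 5 to 8 as in the dam. The binomial test on chromosome 3 therefore cannot tell segregation from a signal tied to sex. A progeny with an unchanged copy from the sire would keep at least 0.5 times the reference. Progeny 5 to 8 lay at 0.31, 0.32, 0.38 and 0.38 times the reference, which argues against a loss passed on by the dam alone. Of the other regions where the parents differed, 2 overlapped the chromosome 3 loss and 1 was a run of 3 probes on chromosome 2, from 70082725 to 70082985, at -0.37 in the sire and 0.37 in the dam. The count of 6 regions was 3 with the normexp correction and 14 or 12 from the arrays of 1 orientation alone.

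**Figure D2:**
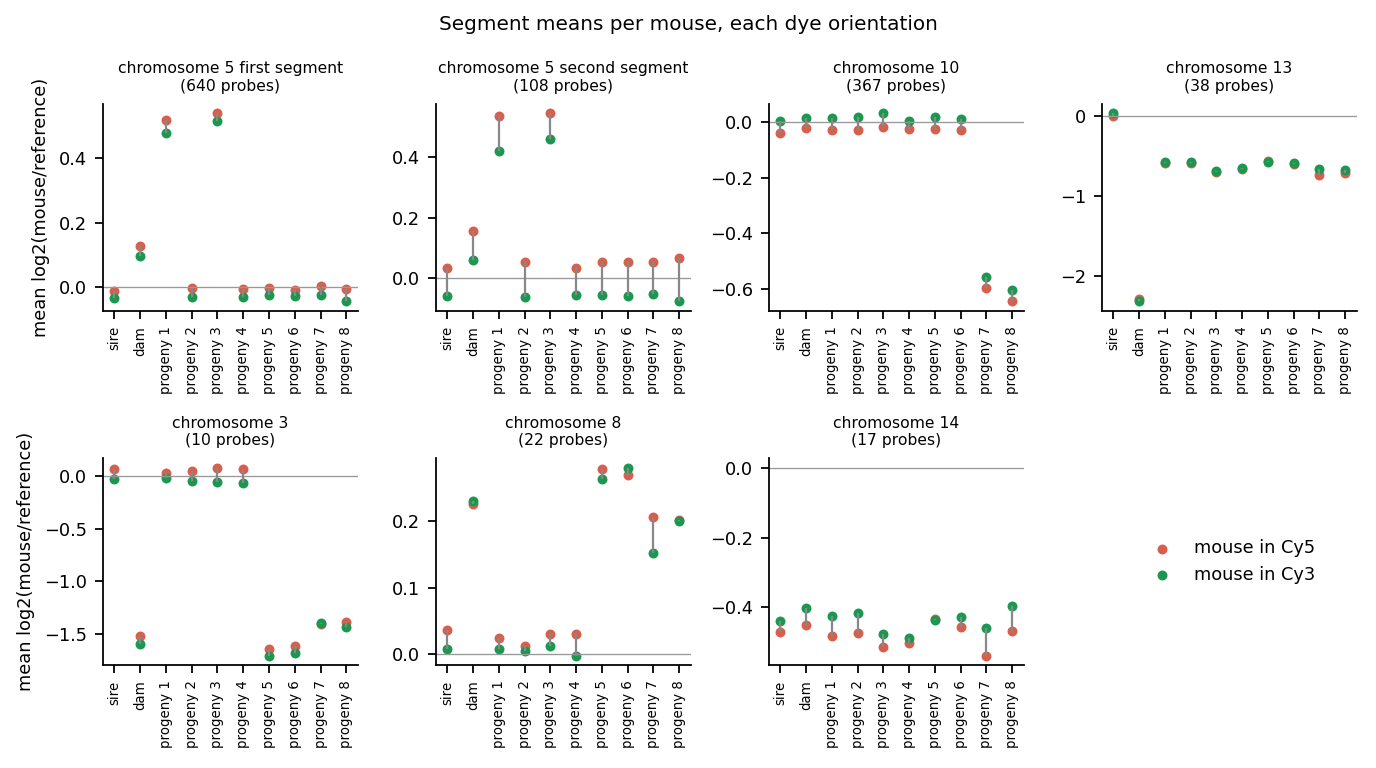
Mean log2 ratio of mouse over reference in 7 segments for each of the 10 mice, with 1 point for each dye orientation and a line joining them. The dam is at -2.30 on chromosome 13 with all progeny between -0.70 and -0.56, and on chromosome 14 every mouse lies below -0.4 on average.

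The third comparison asks where the family differed from the reference male. A segment on chromosome 14, from 53750331 to 53764803 (17 probes), was lower than the reference in every mouse. A loss in the family and a gain in the 1 reference male would read the same and cannot be told apart here. The progeny lay at -0.46 ± 0.03 (SD, n = 8), the sire at -0.45 and the dam at -0.43, or 0.73 and 0.745 times the reference. The probes of this segment had limma adjusted p values from 1.7e-07 to 0.0027. Within 1 Mb, 52 of 200 probes were called, all 52 lower in the progeny, with a median of -0.33. The chromosome 13 loss of the dam gave the other called runs, of which the longest, with 29 probes, lay at -0.65 ± 0.06 (SD, n = 8; limma adjusted p from 1.7e-07 to 0.014).

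In all, 155 of 127025 probes differed between progeny and reference, 54 higher and 101 lower. They included 8 runs of at least 3 neighbouring probes, 6 on chromosome 14 and 2 on chromosome 13, and all 8 were lower. The remaining 82 called probes were in no run. Of the 155, 108 had the same sign in both parents. Most higher calls were lost without progeny 2, 4, 5 or 6 or with slide as a random block. Counts were 14 higher and 89 lower (103 in all) without progeny 2, 13 and 88 (101) without progeny 5, and 14 and 90 without progeny 6. They were 22 and 86 without progeny 4, and 10 and 90 (100) with slide as a random block. Higher calls stayed at 41 without progeny 1, 49 without progeny 3 and 47 without progeny 7, and were 89 without progeny 8. Without progeny 8 the count was 3006, of which 2917 were lower, and it was 688 with no minimum change and 5220 or 5617 from the arrays of 1 orientation alone.

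Against the reference, 1480 intervals were called in the 10 mice, 373 gains and 1107 losses. Gains were 680 from the Cy3 arrays alone and 86 without the 2 progeny of the last slide, and losses were 1718 from the Cy5 arrays alone. The sire had 80 and the dam 122. The progeny had 160 ± 94.8 (SD, n = 8), from 7 in progeny 7 to 342 in progeny 8. Losses made up 97.2% to 98.7% of the intervals in progeny 1 to 6, while progeny 8 had 285 gains and 57 losses. Most intervals were short, 978 of them of 3 probes, and 96.4% had under 10. Against the family median, 1111 intervals were called where orientation noise alone gave 39, and progeny 7 and progeny 8 had 205 and 632 of the 1111. Since progeny 7 had 7 intervals against the reference, most of its 205 were departures from the family median without a call against the reference. Orientation noise leaves out whatever both arrays of a mouse share. The contrast therefore does not tell copy number from another property of the DNA sample. The noise count was 1 with normexp, 3 without dim probes and 17 from the deposited table, where the calls were 980, 1070 and 1090. With at least 10 probes the counts were 44 and 2.

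**Figure D3:**
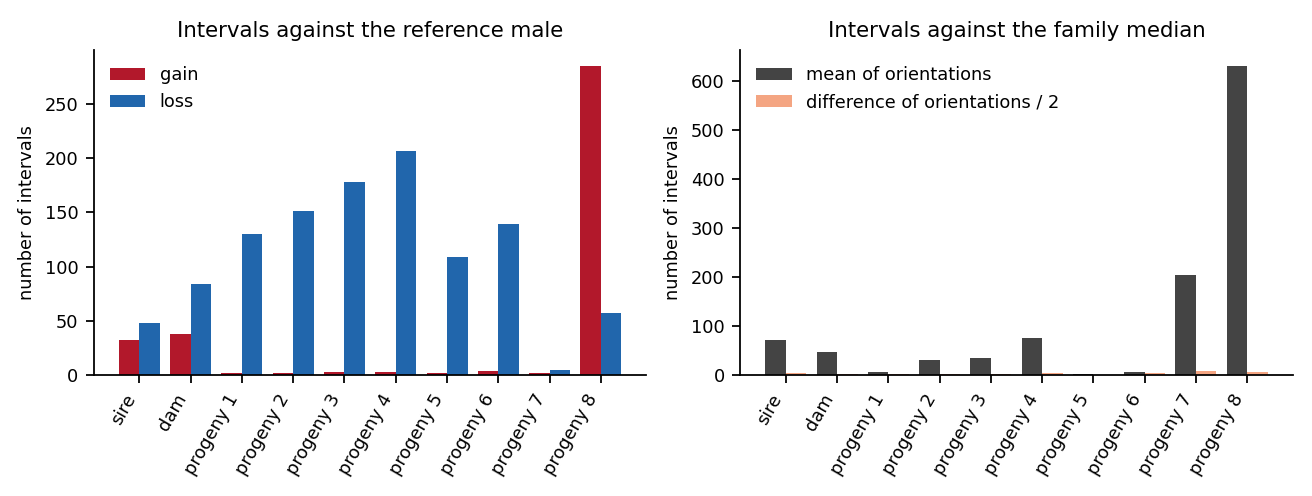
Number of called intervals in each mouse. The left panel gives gains and losses against the reference male, and the right panel intervals against the family median beside those from the difference between orientations divided by 2. Progeny 8 has 285 gains and 632 intervals against the family median, where the noise gives 7.

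The last comparison set the 8 progeny against the 2 parents. No probe passed limma's test, and 99 probes had an unadjusted p under 0.05 with a difference of at least 0.25. Without the 2 progeny of the last slide, an alternative chosen after seeing the data, 386 probes passed, 43 higher and 343 lower in the progeny. Both parents were on a slide of their own, so generation and slide cannot be told apart.

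The 2 orientations of a mouse had a Pearson correlation across probes from -0.49 to 0.34, with a median of 0.02. Arrays of different mice in the same orientation had a median of 0.69, and the lowest was -0.22. After the median over mice was removed from each orientation, the 2 arrays of a mouse correlated at 0.13 to 0.90, with a median of 0.30. Opposite orientations of different mice correlated at -0.55 to 0.72, with a median of -0.039, and the highest of these exceeded 9 of the 10 values within a mouse. These values are across probes, which are not independent replicates.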

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

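The tests of slide, array brightness, generation, copy number at each site and DNA of other mice, and the component shares after centring, were chosen only after the result was seen. Progeny 8 stood apart from the other progeny in 3 of 17 sets of values examined, and chance alone sets a mouse apart in about 1 of 20 such sets. The 17 sets come from the same mice and are not independent, so the 3 are not separate departures from chance. It had 285 gains, noise between neighbouring probes of 0.0786, and 632 intervals against the family median.

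The X and Y probes entered no main comparison, and 5 mice differed there from the reference male. The median log2 X ratio was 0.96 in the dam and 0.97, 0.98, 0.97 and 0.98 in progeny 5, 6, 7 and 8. The median log2 Y ratio was -3.99 in the dam and -3.78, -4.06, -4.47 and -4.68 in progeny 5, 6, 7 and 8.

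The short intervals followed a graded profile over the 10 mice. The 2 leading components of 3342 isolated probes outside every interval accounted for a median of 95.8% of the sum of squares of the 700 regions under 10 probes. The median was 95.1% after the mean over mice was removed, beside 15.7% and 18.0% for random profiles. Random profiles were not picked by calls, however, and progeny 8 lay highest on both components, at 0.444 and 0.754. A change in progeny 8 alone would thus give a high share whatever its cause. A genome-wide component of each DNA sample may underlie most short intervals, but the excess over random profiles does not decide it. Slide stays open as the source of this profile. Of the 105 ways to pair the 8 progeny only the real slides, 1 way or 0.952%, brought mates as near in this profile (exact permutation p = 0.0095, the smallest possible). In 4 ways the mean correlation over all autosomal probes was as high (exact permutation p = 0.038). Slide mates, however, always had the same X and Y pattern, that of males in progeny 1 to 4 and of females in progeny 5 to 8. Many of the 105 pairings mix these patterns, so neither p can tell slide from sex, which stays open too. Progeny 1 and 3 at 0.865 and progeny 2 and 4 at 0.878, on different slides, correlated above slide mates 1 and 2 at 0.808 and 3 and 4 at 0.817. The interval counts of slide mates differed 1.16-fold, 1.15-fold, 1.29-fold and, on the last slide, 48.9-fold. Generation is argued against as the whole source, since 2.23% of the squared differences between mice in this profile lay between parents and progeny, but a part stays open, since the sire at -0.252 and the dam at -0.108 on the first component lay outside progeny 1 to 6, at -0.386 to -0.312, with progeny 7 and 8 at 0.0458 and 0.444. Dim arrays stay open too, since the 2 mice with the dimmest reference channel were progeny 7, with 7 intervals, and progeny 8, with 342, and so does probe GC content, which was not tested. In the longer segments the share before and after centring was 55.7% and 97.6% on chromosome 10 and 88.8% and 59.1% on chromosome 14. It was 65.3% and 27.4% on chromosome 13, 59.9% and 25.5% on chromosome 3, and 64.3% and 20.2% on chromosome 8. On chromosome 5 it was 23.9% and 8.54%, then 26.7% and 7.92%, with 95% of random profiles under 52.7% and 57.1%. Of these segments those on chromosome 5 lay below on both measures, chromosomes 10 and 14 above on both, and chromosomes 3, 8 and 13 changed side. For no segment does the share decide the cause, since it depends on which mice carry the change. The carriers on chromosome 10, progeny 7 and 8, lay highest on the first component. Those on chromosome 5, progeny 1 and 3, lay at -0.312 and -0.367. An equal gain in these 2 mice alone would give a low share whatever its cause.

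Gains shared by the sire, the dam and progeny 8 were called at 25 short sites on 11 chromosomes, with medians of 0.42, 0.49 and 1.00 in these mice. The 7 other mice were graded, with medians from -0.45 in progeny 4 to 0.20 in progeny 7. Sites on different chromosomes had a median correlation of 0.981 over the 7 other mice, which decides nothing about the 3 called mice. The values of the 7, fitted on the components of isolated probes, predicted medians of 0.25 in the sire, 0.57 in the dam and 1.53 in progeny 8, leaving medians over sites of 42.6%, -19.7% and -57.1% of the gain, so a copy number change at each site stays open. A bright multi-copy sequence elsewhere is argued against by the reference channel, where the median probe of these sites lay at percentile 19.7 of brightness. What else sets this profile stays open.

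The dam lay at 0.11 in both chromosome 5 segments gained in progeny 1 and progeny 3, outside the range of uncalled stretches of equal size. DNA of either progeny in the sample of the dam would need a share of at least 18.2%, or 13.1% at 2 SD of equal stretches, and these 2 progeny had log2 Y ratios of 0.02 and -0.04. On the linear scale the Y signal of the dam was 6.29% of the reference over 3 probes, beside 3.89% to 7.28% in progeny 5 to 8, which argues against it. A gain in part of the cells of the dam and an error on the bench that affects both of its arrays were not tested, and the cause stays open.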

How the results depend on the processing

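The choices of at least 10 probes, of leaving out the last slide and of including X and Y probes were made only after the result was seen, and the other alternatives before the data were examined. For 34 pairs of a named segment and a mouse, those called and the dam on chromosome 5, all 204 values recomputed with other signals, centring, filters or single orientations kept their sign, and 176 moved by less than their spread. The calling rule already required the same sign in each orientation. The single-orientation values of called pairs could therefore hardly change sign, and are no check of it. Other mice were not recomputed. Total counts of calls within 1.5 times the reported one are not listed. Intervals against the reference had 680 gains and 1526 losses from Cy3 arrays and 471 and 1718 from Cy5 arrays. The noise count of 39 beside the intervals against the family median was 1 with normexp, 3 without dim probes, 17 from the deposited table, 10 with at least 5 probes, 5 with a mean of at least 0.5, 2 with at least 10 probes and 28 without the last slide. With at least 5 probes, intervals fell to 284, those against the family median to 292 and progeny-only regions to 68. With a mean of at least 0.5 the same counts were 435, 347 and 192, and with at least 10 probes 53, 44 and 12. Without the last slide, intervals against the family median were 256, progeny-only regions 64, and called probes 3782 for progeny against reference and 386 for progeny against parents. A stricter minimum lowers the counts of intervals and regions by construction. Leaving out mice does so for progeny-only regions, of which 64 of 322 were not called in progeny 8. Otherwise the cause was not tested. Regions with a parental difference were 14 from Cy5 arrays, 12 from Cy3 arrays, 3 with normexp and 22 at a difference of 0.25. Probes of progeny against reference were 688 with no minimum change, 5220 from Cy5 arrays, 5617 from Cy3 arrays, where the dye effect does not cancel, and 100 with slide as a random block. Leaving out each progeny in turn gave 101 to 3006, the highest without progeny 8 and the lowest without progeny 5, and 0 in every case for progeny against parents. No paired analysis was possible because the groups share fewer than 2 replicate numbers. The GC correction and the gene list test were not run. Median spot signal was 14.6 to 24.6 times background in the dimmer channel, which limits deep losses most. The dam on chromosome 13 lay at -2.30, and at -1.66 with normexp. On the linear scale alone, this moved all 8 progeny past the midpoint between the parents to the side of the dam.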

Other observations

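Some short regions did not share the graded profile of the others. Of the 700 regions under 10 probes, 10 had under 50% of their sum of squares over mice accounted for by the 2 components of isolated probes. One was a loss in progeny 5 on chromosome 4, from 41145606 to 41146127 (3 probes), at -0.87, where the other mice lay between -0.01 and 0.08. In others, nearby runs went in opposite directions in the same mouse. On chromosome 4, progeny 3 lay at 0.43 from 30869139 to 30870442 and at -0.51 from 30874313 to 30874508. On chromosome 2, the sire lay at -0.37 from 70082725 to 70082985 and at 0.46 from 70085479 to 70085630. These values had the same sign in both orientations, but some other mice did not. Progeny 6 lay at 1.40 and -0.13 in the first chromosome 2 run, and the sire at 0.29 and -0.52 in the second chromosome 4 run. The probes there thus differed between dyes.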
